A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

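The series held 18 RNA-seq libraries of cultured liver endothelial cells, 12 from human hepatic sinusoidal endothelial cells and 6 from mouse sinusoidal endothelial cells. Per the labels, the cells were plated on gels with a stiffness of 0.2 kPa (soft) or 32 kPa (hard). The human cells were sampled at 6 h and at 12 h and the mouse cells at 12 h, which makes 6 groups of 3 libraries. Per the labels, the human cells were company-derived and grown in endothelial growth medium. The growth text of the mouse samples describes human cells, so the culture of the mouse cells is not given in the sources used here. The origin of the replicates (donor, isolation, passage or dish) is not stated, so the p-values measure only the spread between these samples, which may be technical.

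The deposited data were 2 count tables and 3 tables of gene statistics. The count tables deposited by the authors hold raw read counts per gene and library, whole numbers with no normalisation. Per the submitters' processing notes, TopHat2 2.1.0, featureCounts and edgeR were used and the builds were GRCh38, hg38 and mm10. The order of these tools, the strand of counting and any filters are not given in the sources used here. Counts of overlapping or antisense genes are therefore uncertain. The deposited count tables also give a length in bases per gene, which was used only in a check of length bias. The authors' deposited tables of statistics give a log2 fold change and log2 CPM per gene. The score column of the authors' deposited tables is a likelihood ratio statistic, per the file headers. The p-value and adjusted p-value columns of the authors' deposited tables are those of an edgeR likelihood ratio test, whose dispersion and filters are not given in the sources used here. These tables served only as a comparison.

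Depth per library was 35124235 to 61248989 counts in human and 37863164 to 46877566 in mouse. The deposited counts covered 64253 human and 23337 mouse genes. After the low-count filter of edgeR (filterByExpr, minimum count 10, minimum total 15), 20950 human and 14100 mouse genes were tested. The biological coefficient of variation in edgeR was 7.06% in human and 8.46% in mouse. Levels in CPM were computed with library sizes scaled by the trimmed mean of M-values (TMM) and are given as mean ± SD of 3 libraries. Gene coordinates are those of the count tables.

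Differences were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM scaling. All 12 human libraries were fitted together and the 6 mouse libraries apart. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The gel comparisons give hard over soft, the time comparisons 12 h over 6 h on each gel, and the interaction gives the gel effect at 12 h minus that at 6 h. All tests were two-sided. Errors of log2 fold changes are standard errors (SE), derived as the absolute log2 fold change over the square root of the edgeR F statistic.

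In total, 36 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over lists holding at least 3 tested genes. The same test was run with an estimated correlation, and fry asked whether the genes of a list moved, on balance, one way. For each list the members called over all genes and those called when adjusted over the list alone were counted. The tests of the comparisons, the lists, all alternatives but an added one and the rule for naming genes were chosen before the data were examined, while that alternative and some checks in the closing section were chosen later.

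The rule named, per gel comparison, the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, without placeholder names. It added the 2 smallest adjusted p-values among called members of each list tied to the study's question, up to 2 called members of any other list, and a fixed set (CXCL1, CXCL8, CXCL2, CYR61, CTGF, ANKRD1, HK2, PFKFB3, LDHA, LYVE1, STAB1 and STAB2). For the interaction it took 5 genes per direction, for each time comparison 3 per direction, and for each correlation 5 called genes per direction.

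Gel effects were compared between times, and between species at 12 h, by Pearson and Spearman correlation across genes. Genes are not independent replicates, so the correlations were set against the 100 ways of splitting the libraries of both comparisons into 3 and 3. Human and mouse genes were paired by symbol, since no table of orthologs was used here.

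Whether equal replicate numbers pair the libraries was checked from the data, because the labels do not say. In mouse, the correlations between a hard library's deviation from its group mean and that of the soft library of equal number were 0.350, 0.573 and 0.117, all over the 0.1 set for pairing. Libraries of unequal number ran from -0.548 to 0.262 in mouse and reached 0.488 in human, so the check does not establish pairing. The mouse fit with a replicate block is given where it changes a call.

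The tests were checked on simulated data in which 100 genes were changed by a log2 fold of 0.5 and 100 by 1. The changed genes had a mean log2 CPM of at least 3, and the simulated noise was independent between libraries. edgeR called 97%, 96% and 93% of the smaller changes for human 6 h, human 12 h and mouse, and 100% of the larger ones, with 13, 20 and 15 false calls. In each comparison the false calls made up a larger share of the simulated calls than the 0.05 aimed at. The alternatives were size factors by the median of ratios, a strict filter and none, DESeq2 1.42.0, a fold limit, 6 libraries alone, the replicate block and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9. Some genes that the naming rule selected are not reported here. Levels of X-inactivation and Y-linked genes were not reported for these primary cells.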

Results

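Gene expression was measured by RNA-seq in liver sinusoidal endothelial cells, the fenestrated endothelium lining the liver capillaries, on soft (0.2 kPa) and hard (32 kPa) gels. The series title sets soft against hard gels, so the question was which genes respond to the stiffness under the cells. Each of the 6 groups held 3 libraries. Human soft libraries held 35124235, 41604464 and 45448668 counts at 6 h, and 56191746, 47718031 and 40730652 at 12 h. Human hard libraries held 42996360, 54694256 and 51540681 counts at 6 h, and 50136964, 61248989 and 55329535 at 12 h. Mouse libraries, all at 12 h, held 44960758, 37863164 and 40826430 counts on soft and 43511551, 45276564 and 46877566 on hard gels. In human the first principal component (30.3% of the variance) parted the times and the second (15.7%) the gels. In mouse the first (27.0%) set replicate 2 of both gels apart from the others, and the second (23.2%) parted the gels.

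The human cells expressed endothelial genes beside very abundant fibrillar collagen. Mean levels over the 12 human libraries were 39.4 CPM for the VEGF receptor KDR, 29.2 CPM for the junction gene PECAM1 and 72.2 CPM for the angiopoietin receptor TEK. Von Willebrand factor (VWF), another endothelial gene, was low, between 0.546 and 2.24 CPM. The collagen I chains COL1A1 and COL1A2 reached 14203 and 10640.3 CPM, and PDGFRB, a pericyte and fibroblast receptor, 359 CPM. The sinusoidal scavenger receptors were low, with LYVE1 at 1.75 CPM, STAB1 at 8.20 CPM and STAB2 at 0.171 CPM. The cell type is that of the labels. The collagen, PDGFRB and scavenger receptor levels put the identity of the human cells as sinusoidal endothelium in doubt. This limits what their comparison with the mouse cells can show. In the mouse cells, Lyve1 stood at 3334 CPM, Stab1 at 1391 CPM, Stab2 at 353 CPM and Col1a1 at 1.18 CPM. Albumin (Alb), the main hepatocyte product, stood at 271 CPM in mouse, and human ALB at 0.0215 CPM.

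At 6 h on the hard gel, human cells raised most of the mechanosensitive targets of YAP and TEAD, the secreted vasoconstrictor EDN1 and the checkpoint ligand CD274. Neutrophil-attracting chemokines (CXCL1, CXCL8), the CCR6 ligand CCL20 and sterol synthesis genes such as MSMO1 rose with them. The actin-linked genes VCL and ACTN1 and a part of the immediate early genes (FOSL1, DUSP1) were also higher. The heme oxygenase HMOX1, the growth factor TGFB3 and a part of the cytosolic ribosomal protein genes fell. With an estimated correlation, camera (Benjamini-Hochberg) called 0 lists at this time.

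Of 22 tested YAP and TEAD targets 14 rose and 0 fell, with 17 up when adjusted over the list alone. Its camera test gave a Benjamini-Hochberg adjusted p = 4.83e-14, and adjusted p = 0.0844 with an estimated correlation. With 1 library left out, only 10 to 12 of the 22 targets were called higher, 10 of them without soft replicate 1. ANKRD1 (ENSG00000148677), a nuclear ankyrin repeat protein on GRCh38 chromosome 10 (90912096 to 90921276), rose 7.12-fold. Its level was 70.0 ± 10.5 CPM (SD, n = 3) on hard against 9.85 ± 0.916 CPM (SD, n = 3) on soft gels. CYR61 (ENSG00000142871, chromosome 1, 85580761 to 85583962) and CTGF (ENSG00000118523, chromosome 6, 131948176 to 131951373), both matricellular proteins, rose 5.56-fold and 5.15-fold. CTGF reached 1319.9 ± 156 CPM against 256 ± 13.6 CPM (SD, n = 3). EDN1 (ENSG00000078401, chromosome 6, 12290363 to 12297194) had a log2 fold change of 2.70 (SE 0.122; edgeR, Benjamini-Hochberg adjusted p = 5.29e-13). CD274 (ENSG00000120217, chromosome 9, 5450503 to 5470566) rose from 14.6 ± 0.905 to 50.4 ± 4.99 CPM (SD, n = 3). The Wnt antagonist DKK1, the angiomotin AMOTL2 and the neurotrophin BDNF were further rises under the naming rule (mean log2 CPM of at least 3, no overlap), at log2 1.99, 1.63 and 1.48. In all 16 largest rises and falls the 3 hard libraries lay wholly above or below the 3 soft ones, as the naming rule required.

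Among sterol genes 16 of 19 rose, 0 fell, and 16 rose when adjusted over the list alone. The camera Benjamini-Hochberg adjusted p = 1.2e-14 became adjusted p = 0.0844 with an estimated correlation. The sterol oxidase MSMO1 rose by log2 0.83. Of 15 chemokines 6 rose and 0 fell, with 10 up when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 4.29e-06, and adjusted p = 0.183 with an estimated correlation). CXCL1 (ENSG00000163739, chromosome 4, 73869393 to 73871242) stood at 789 ± 41.5 CPM on hard and 419 ± 22.2 CPM on soft gels (SD, n = 3), and CXCL8 at 3842 ± 168 and 2086 ± 107 CPM. CCL20 rose by log2 1.18 and CXCL2 by log2 0.29. NF-kB targets rose in 9 of 22 cases and fell in 1, and in 10 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000409, and adjusted p = 0.416 with an estimated correlation). The NF-kB regulator NFKBIZ rose by log2 0.55 and the leukocyte receptors VCAM1 and SELE by 0.45 and 0.90.

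Actin and SRF targets rose in 11 of 20 cases, with 0 falls and 12 rises when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.74e-05, and adjusted p = 0.407 with an estimated correlation). Vinculin (VCL) rose by log2 0.52 and the actin crosslinker ACTN1 by 0.47. Integrin and focal adhesion genes rose in 4 and fell in 1 of 19 cases, and in 7 and 1 when adjusted over the list alone, but the list was not called (camera, Benjamini-Hochberg adjusted p = 0.051). The kindlin FERMT2 rose by log2 0.44 and the adaptor LIMS1 changed by log2 -0.33. Matrix and remodelling genes rose in 7 and fell in 1 of 21 cases, and in 8 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000189, and adjusted p = 0.407 with an estimated correlation). The matricellular THBS1 rose from 849.9 ± 7.24 to 1722 ± 177 CPM (SD, n = 3). The metalloproteinase inhibitor TIMP3 rose by log2 0.53.

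Interferon response genes rose in 9 of 18 cases at 6 h, 0 fell, and 13 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.06e-06, and adjusted p = 0.328 with an estimated correlation). MX1, an antiviral GTPase, rose by log2 1.33. Immediate early genes rose in 8 of 16 cases, also when adjusted over the list alone, with 0 falls (camera, Benjamini-Hochberg adjusted p = 0.00122, and adjusted p = 0.447 with an estimated correlation). The AP-1 subunit FOSL1 rose by log2 0.51 and the phosphatase DUSP1 by 0.37. Nuclear pore genes rose in 7 of 27 cases and in 11 when adjusted over the list alone, with NDC1 at log2 0.27 and NUP98 at 0.21 (camera, Benjamini-Hochberg adjusted p = 0.00059, and adjusted p = 0.183 with an estimated correlation). Heat shock genes rose in 4 of 10 cases and pan-endothelial genes in 3 of 14, or in 6 and 4 when adjusted over the list alone. Their camera Benjamini-Hochberg adjusted p = 0.00398 and 0.0354 became adjusted p = 0.178 and 0.407 with an estimated correlation. The chaperone HSPA8 rose by log2 0.45 and the TGF-beta co-receptor ENG by 0.29. Cytosolic ribosomal protein genes fell in 4 of 22 cases and in 9 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.9e-05, and adjusted p = 0.386 with an estimated correlation). RPL7 and RPL15 changed by log2 -0.25 and -0.19. Ribosomal RNA genes, mitochondrial ones included, held 1.09% to 1.36% of counts in the soft and 0.932% to 1.04% in the hard 6 h libraries, without overlap. A link of this share to the gene changes was not tested.

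Glycolysis was not called as a list at 6 h, although 5 of 22 genes rose, 0 fell and 6 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.139). The glucose transporter SLC2A1 rose from 269.8 ± 23.7 to 373 ± 26.2 CPM (SD, n = 3) and the hexokinase HK2 by log2 0.34. PFKFB3 and LDHA were not called, at log2 -0.05 and 0.00 (edgeR, Benjamini-Hochberg adjusted p = 0.637 and 0.963). Of 6 tested sinusoidal markers 0 rose and 1 fell, GATA4 at log2 -0.22, a call that was lost with the replicate block and without a filter. LYVE1, STAB1 and STAB2 were not called at log2 -0.60, -0.10 and 0.44 (edgeR, Benjamini-Hochberg adjusted p = 0.102, 0.622 and 0.765). Angiocrine factors rose in 6 and fell in 2 of 15 cases, with a median log2 of -0.04 but a mean of 0.27 and a camera direction up (Benjamini-Hochberg adjusted p = 0.144). Tip cell genes rose in 4 and fell in 2 of 9 cases, with a median of -0.18, a mean of 0.11 and a camera direction up (Benjamini-Hochberg adjusted p = 0.677). The tip cell gene ESM1 rose by log2 1.23 and KLF2, the flow-induced factor, by 0.71, while the Notch target HEY1 changed by -0.79.

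In all, edgeR called 2500 genes at 6 h, 1475 up and 1025 down, of which 106 and 44 changed at least by log2 1. Among the falls were the ETS factor ETV1 at log2 -1.03, TGFB3 at -0.96, the ligase RNF144A at -0.95, HMOX1 at -0.84 and the GTPase RHOU at -0.83. AKR1C1, at -0.90, has near-identical relatives, and MT-RNR1, at -0.81, is a ribosomal RNA, so both values are uncertain. The groups did not overlap in 6232 genes, 29.7% of those tested, where chance gives 10%. The count was 1655 without soft replicate 1, 1450 without soft replicate 2, 1503 without hard replicate 1 and 1656 without hard replicate 2. Leaving out 1 of several libraries ended the calls of GATA4, CXCL2, ENG, RPL7 and RPL15, hard replicate 2 that of NDC1 and soft replicate 2 that of NUP98. The fewest called list members were 2 nuclear pore, 1 heat shock, 0 pan-endothelial and 5 immediate early genes without soft replicate 2, 4 rising matrix and 1 rising integrin genes without soft replicate 1, and 4 interferon, 7 actin and 1 ribosomal protein genes without hard replicate 1.

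**Figure D1:**
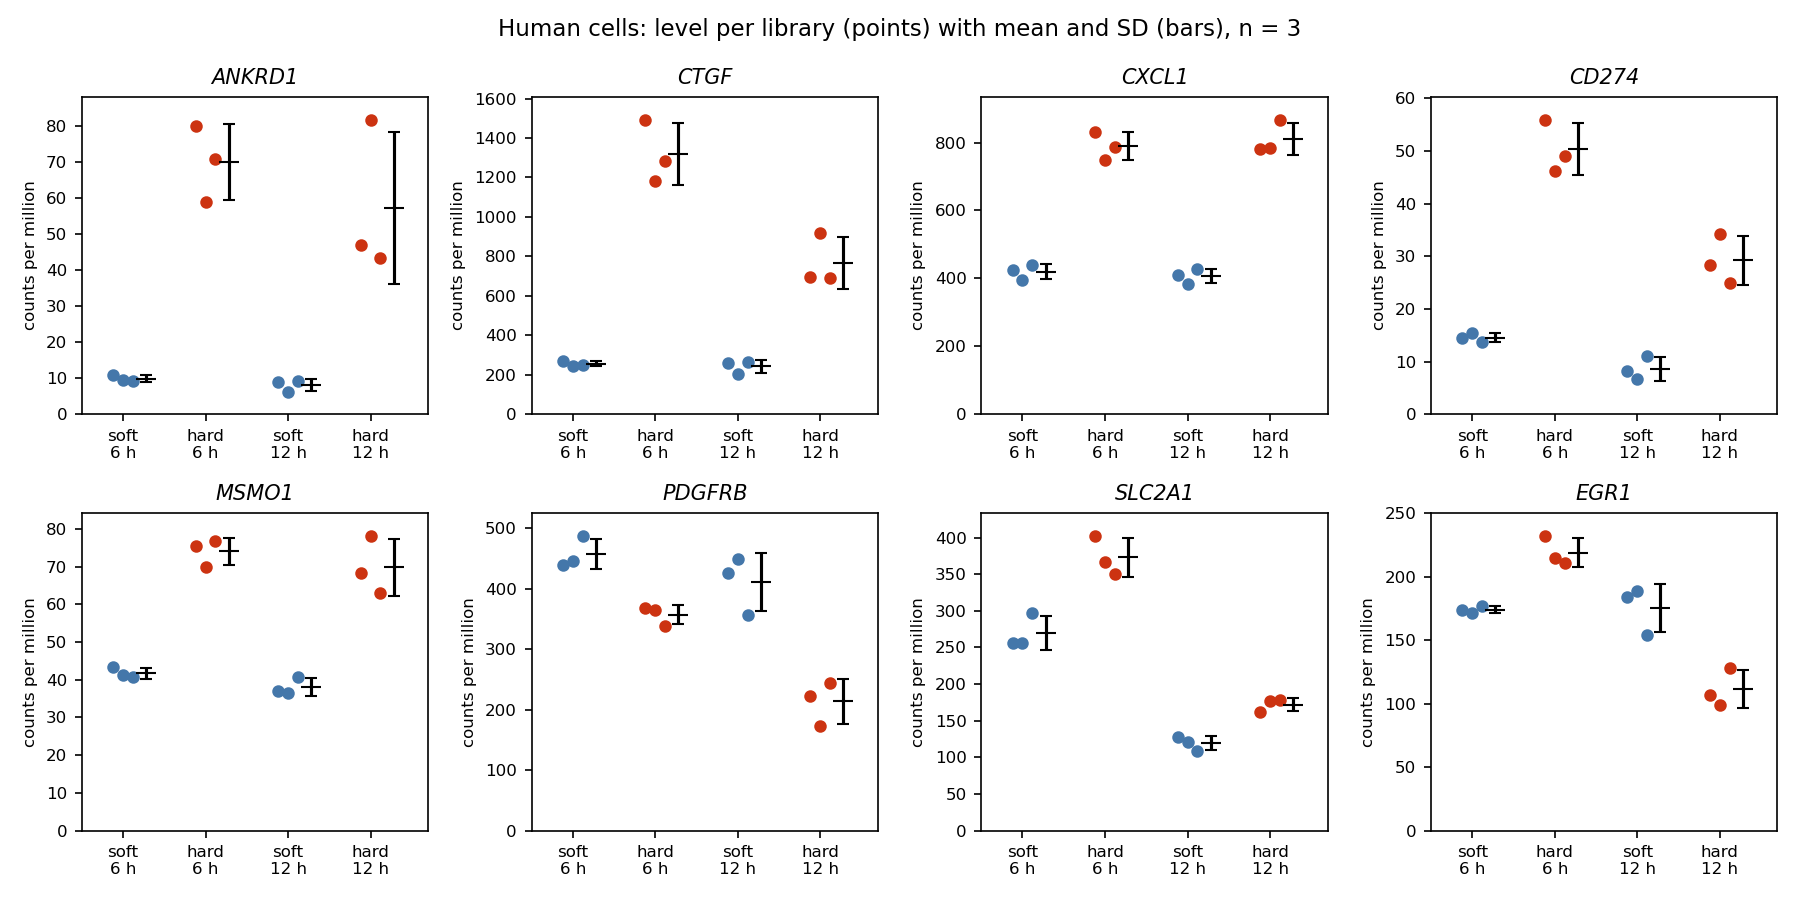
CPM per human library of 8 genes on soft (blue) and hard (red) gels at 6 h and 12 h, with bars for the mean ± SD of 3 libraries. ANKRD1 averaged 70.0 CPM on hard against 9.85 CPM on soft gels at 6 h, while EGR1 averaged 111 CPM on hard against 175 CPM on soft gels at 12 h.

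At 12 h, as at 6 h, most YAP and TEAD targets and sterol synthesis genes, a part of the chemokines and nuclear pore genes and the pattern recognition protein PTX3 were higher on the hard gel. Most cell cycle genes (RRM2, MCM4) were higher as well. A part of the immediate early genes, such as EGR1, was now lower on the hard gel. The matrix calcification inhibitor MGP and a part of the TGF-beta response genes (TGFB1, PMEPA1), of the markers shared with stellate cells and fibroblasts (PDGFRB, DCN) and of the ribosomal protein genes fell. With an estimated correlation, camera (Benjamini-Hochberg) called 0 lists here too.

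Of 22 YAP and TEAD targets 15 rose and 1 fell at 12 h, and 18 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.15e-11, and adjusted p = 0.0613 with an estimated correlation). ANKRD1 rose 7.02-fold, from 8.18 ± 1.68 to 57.3 ± 21.1 CPM (SD, n = 3). CYR61 rose 3.5-fold and CTGF 3.17-fold, CYR61 to 315 ± 54 CPM (SD, n = 3). The checkpoint ligands CD274 and PDCD1LG2 rose by log2 1.77 and 1.52, the oxytocin receptor OXTR by 1.58 and DKK1 by 1.56. PTX3 rose 2.84-fold (edgeR, Benjamini-Hochberg adjusted p = 1.71e-12) and reached 930.4 ± 82.5 CPM against 328 ± 26.6 CPM (SD, n = 3). Sterol genes rose in 17 of 19 cases and in 18 when adjusted over the list alone, with 0 falls (camera, Benjamini-Hochberg adjusted p = 2.92e-14, and adjusted p = 0.0613 with an estimated correlation). MSMO1 rose by log2 0.88.

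Cell cycle genes rose in 20 of 29 cases at 12 h and in 23 when adjusted over the list alone, with 0 falls (camera, Benjamini-Hochberg adjusted p = 4.88e-14, and adjusted p = 0.187 with an estimated correlation). The nucleotide reductase RRM2 rose from 34.0 ± 1.93 to 77.0 ± 12.7 CPM (SD, n = 3) and the helicase subunit MCM4 by log2 0.91. Replication-dependent histones had 0 rises and 1 fall among 6, with a median log2 of -0.36 and no call for the list (camera, Benjamini-Hochberg adjusted p = 0.116). Nuclear pore genes, which carry traffic through the nuclear envelope, rose in 15 of 27 cases, with 0 falls, and in 19 with 1 fall when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.89e-08, and adjusted p = 0.0613 with an estimated correlation). NUP155 rose from 28.7 ± 0.991 to 43.2 ± 3.85 CPM (SD, n = 3) and NDC1 by log2 0.52. Cytosolic ribosomal protein genes fell in 11 of 22 cases and in 17 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.89e-06, and adjusted p = 0.387 with an estimated correlation), with RPL10 at log2 -0.27. Of 13 mitochondrially encoded genes 8 rose, also when adjusted over the list alone, with MT-CO1 at log2 0.28 (camera, Benjamini-Hochberg adjusted p = 0.000715, and adjusted p = 0.407 with an estimated correlation).

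Chemokines rose in 9 of 15 cases at 12 h and in 10 when adjusted over the list alone, with 0 falls (camera, Benjamini-Hochberg adjusted p = 1.89e-06, and adjusted p = 0.174 with an estimated correlation). CXCL1 rose 1.99-fold, from 407 ± 21.2 to 810.5 ± 48.4 CPM (SD, n = 3), CXCL8 by log2 0.70 and CXCL2 by 0.30. NF-kB targets split into 6 rises and 7 falls among 22, or 6 and 9 when adjusted over the list alone, and were not called as a list (camera, Benjamini-Hochberg adjusted p = 0.849). The cytokine IL6 rose by log2 0.50 and the subunit NFKB1 changed by -0.30. The NF-kB split was 3 and 4 without soft replicate 2, 3 and 6 without hard replicate 1, and 3 and 10 without hard replicate 3. Interferon genes rose in 11 of 18 cases, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000212, and adjusted p = 0.402 with an estimated correlation), with MX1 at log2 1.70. Immediate early genes fell in 8 and rose in 1 of 16 cases, and in 9 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00394, and adjusted p = 0.576 with an estimated correlation). The transcription factor EGR1 stood at 111 ± 15.2 CPM on hard and 175 ± 18.8 CPM on soft gels (SD, n = 3), and EGR2 changed by log2 -0.89.

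TGF-beta and BMP response genes fell in 7 and rose in 1 of 12 cases at 12 h, and in 9 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00334, and adjusted p = 0.402 with an estimated correlation). The ligand TGFB1 changed by log2 -0.44 and its feedback target PMEPA1 by -0.40. Stellate cell and fibroblast markers fell in 6 of 12 cases, also when adjusted over the list alone, with 0 rises (camera, Benjamini-Hochberg adjusted p = 0.00277, and adjusted p = 0.402 with an estimated correlation). By DESeq2, 4 of these markers were lower already at 6 h. PDGFRB stood at 213.5 ± 36.5 CPM on hard and 411 ± 48.1 CPM on soft gels (SD, n = 3), and the proteoglycan DCN changed by log2 -0.50. Actin and SRF targets rose in 12 and fell in 1 of 20 cases, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000124, and adjusted p = 0.449 with an estimated correlation), with TPM1 at log2 0.50 and VCL at 0.34. Heat shock genes rose in 5 and fell in 1 of 10 cases, and in 6 and 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0103, and adjusted p = 0.174 with an estimated correlation). HSPA8 rose by log2 0.43 and the mitochondrial chaperonin HSPD1 by 0.38.

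Glycolysis genes rose in 7 and fell in 1 of 22 cases at 12 h, and in 7 and 2 when adjusted over the list alone, without a call for the list (camera, Benjamini-Hochberg adjusted p = 0.0509). The lactate transporter SLC16A1 rose by log2 0.56, SLC2A1 by 0.53, HK2 by 0.36 and LDHA by 0.21, while PFKFB3 changed by -0.21. Of 6 sinusoidal markers 0 were called by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2), with a median log2 of -0.35 (camera, Benjamini-Hochberg adjusted p = 0.181). LYVE1 at -0.48, STAB1 at -0.12 and STAB2 at -1.25 were not called (edgeR, Benjamini-Hochberg adjusted p = 0.146, 0.466 and 0.245). Matrix genes rose in 6 and fell in 2 of 21 cases, with a median of -0.04 but a mean of 0.10 and a camera direction up (Benjamini-Hochberg adjusted p = 0.173). THBS1 rose by log2 1.06 and TIMP3 by 0.60. Integrin genes rose in 3 and fell in 5 of 19 cases (camera, Benjamini-Hochberg adjusted p = 0.789), with FERMT2 at log2 0.41 and the tensin TNS3 at -0.46. Capillarization genes fell in 5 of 10 cases, with the laminin LAMA4 at log2 -0.31 (camera, Benjamini-Hochberg adjusted p = 0.128). Among them VWF changed by log2 -0.86, at levels of only 1.01 to 2.24 CPM in the 12 h libraries. Called falls of capillarization genes numbered 3 without soft replicate 1, soft replicate 2 or hard replicate 2, and those of integrin genes 3 without soft or hard replicate 2. Falls of glycolysis genes numbered 4 without soft replicate 3 and 0 without replicate 1 or 2 of either gel, and those of matrix genes 0 without soft or hard replicate 2 and 1 without soft or hard replicate 1.

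In all, edgeR called 4263 genes at 12 h, 2293 up and 1970 down, of which 185 and 87 changed at least by log2 1. Under the naming rule (mean log2 CPM of at least 3, no overlap), the largest falls included RNF144A at log2 -1.18, the protease HTRA3 at -1.11, MGP at -1.09, the deacetylase HDAC5 at -0.95, KLHL24 at -0.95 and PDGFRB at -0.94. AKR1C2, at -0.90, shares near-identical sequence with AKR1C1 and is uncertain. The groups did not overlap in 7036 genes, 33.6% of those tested, where chance gives 10%. Leaving out soft or hard replicate 1 or 2 ended the call of PFKFB3, and hard replicate 3 that of CXCL2. The fewest called list members were 2 ribosomal protein and 3 rising heat shock genes without soft replicate 1, 7 nuclear pore, 6 interferon and 3 fibroblast genes without soft replicate 2, 5 mitochondrially encoded genes without hard replicate 1 and 7 rising actin genes without hard replicate 2.

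**Figure D2:**
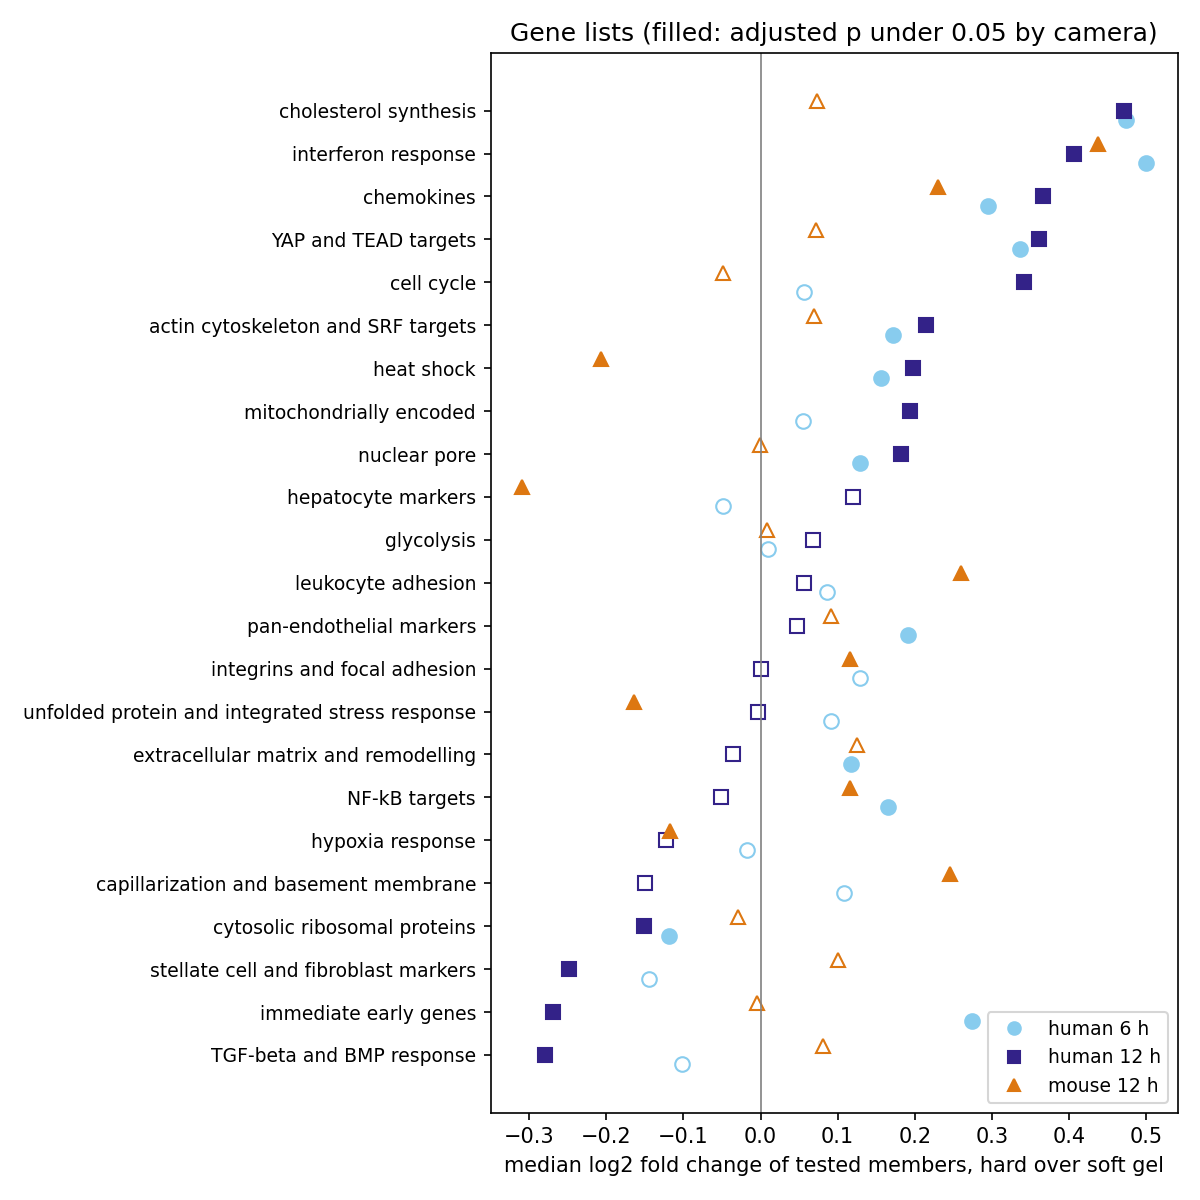
Median log2 fold change, hard over soft, of each gene list in human cells at 6 h and 12 h and in mouse cells at 12 h, with filled symbols for a camera Benjamini-Hochberg adjusted p under 0.05. The sterol synthesis list had a median of 0.47 at both human times, and the immediate early list moved from 0.27 at 6 h to -0.27 at 12 h.

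Whether the gel effect differed between the times was tested by the interaction. The gel effects of MCM10, HELLS and CLSPN, which act in DNA replication, were larger at 12 h, as their levels fell on the soft gel between the times. The gel effects of the immediate early factors EGR1, EGR3 and NR4A1, the cytokine IL11 and EDN1 were lower at 12 h than at 6 h. Cell cycle genes were higher in the interaction in 8 of 29 cases and in 23 when adjusted over the list alone, with 0 lower (camera, Benjamini-Hochberg adjusted p = 3.0e-18, and adjusted p = 0.149 with an estimated correlation). Immediate early genes were lower in 6 of 16 cases and in 14 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.41e-12, and adjusted p = 0.149 with an estimated correlation). NF-kB targets were lower in 2 of 22 cases and in 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.95e-06, and adjusted p = 0.431 with an estimated correlation). YAP and TEAD targets were higher in 2 and lower in 4 of 22 cases, without a call for the list (camera, Benjamini-Hochberg adjusted p = 0.89).

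The gel effect of EDN1 went from log2 2.70 at 6 h to 1.35 at 12 h, an interaction of -1.34 (SE 0.167; edgeR, Benjamini-Hochberg adjusted p = 0.000145). IL11 went from 1.06 to -0.01, EGR1 from 0.33 to -0.66, EGR3 from 0.12 to -0.84 and NR4A1 from 0.23 to -0.64. The sodium-calcium exchanger SLC8A1 went from 0.55 to 1.78, an interaction of 1.24 (SE 0.148; edgeR, Benjamini-Hochberg adjusted p = 9.17e-05). The oxidase AOX1 went from 0.12 to 1.28, MCM10 from 0.37 to 1.55, the helicase HELLS from 0.11 to 1.22 and the checkpoint mediator CLSPN from 0.21 to 1.28. In all, edgeR called 177 genes, 92 higher and 85 lower at 12 h. This count was 83 and 73 without soft 6 h replicates 1 and 2, 73 and 95 without hard 6 h replicates 1 and 2, and 102, 72 and 603 without soft 12 h replicates 1, 2 and 3. It was 85 and 267 without hard 12 h replicates 1 and 3, and the 10 named genes kept their calls in each alternative other than the fold limit of log2 1, under which EGR1, EGR3 and NR4A1 fall short.

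Across 20950 genes the gel effects at both times correlated with Pearson r = 0.385 and Spearman rho = 0.440, and with r = 0.731 over the 10172 genes with a mean log2 CPM of at least 3. In the exact count over 100 splits, on differences of mean log2 CPM, 1 split reached the r = 0.420 of the real one (highest other 0.290), which gives the smallest p such a count allows, 0.01. Genes called at both times numbered 1645, with 995 higher, 641 lower and 9 opposite, where independence gives 161, 96.4 and 251. ANKRD1, CYR61, CD274, CTGF and DKK1 led the shared rises, ranked by the smaller of the effects at both times. RNF144A, TGFB3, KLHL24 and the E3 ligase PELI2 (log2 -0.79 at each time) were among the shared falls. FOS (0.33 and -0.39) and the scaffold NEDD9 (0.48 and -0.29) joined EGR1 among the opposite ones.

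**Figure D3:**
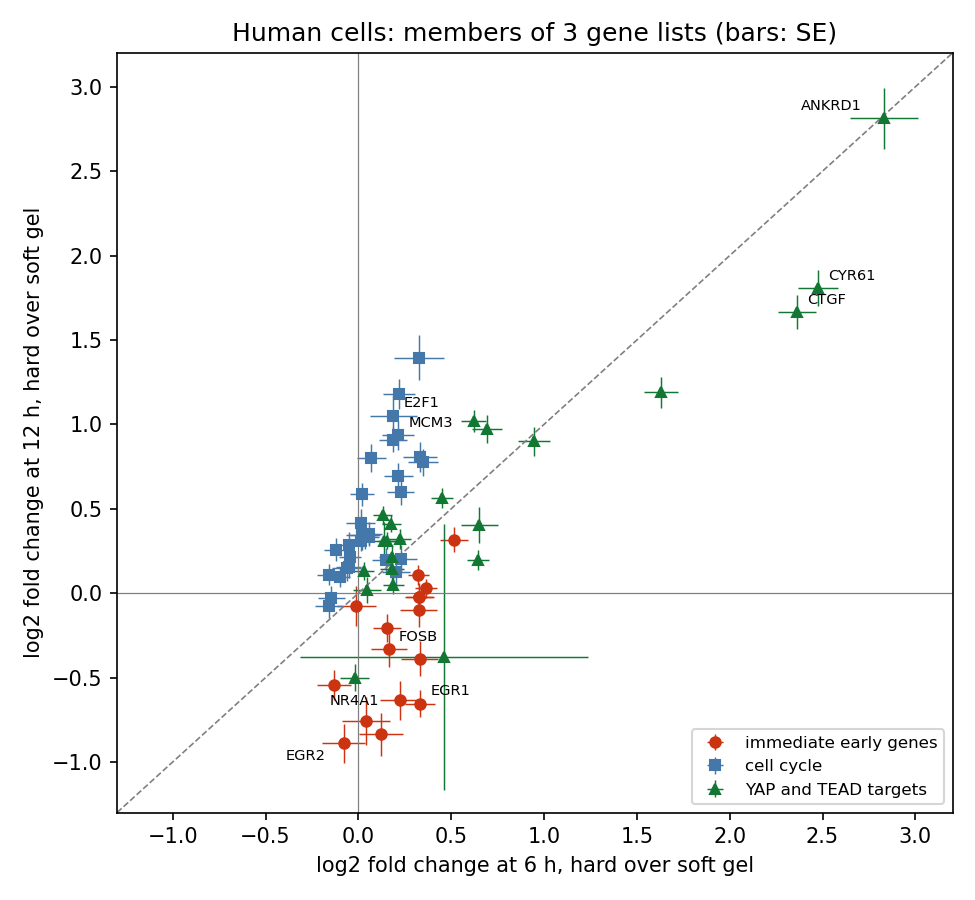
Gel effect (log2 fold change, hard over soft, ± SE) at 6 h (horizontal) and 12 h (vertical) of immediate early (red circles), cell cycle (blue squares) and YAP and TEAD (green triangles) genes, with a dashed line of equality. Immediate early genes lay below the line with a median interaction of -0.42 and cell cycle genes above it with 0.32.

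Between 6 h and 12 h, both gels showed falls of most actin, hypoxia, interferon and immediate early genes. The calcitonin receptor-like receptor CALCRL and the cortisol-regenerating enzyme HSD11B1 rose on both, and the phosphodiesterase PDE3A and TGFB3 fell. Cell cycle genes fell in 23 of 29 cases on the soft gel, with 0 rises and 24 falls when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.7e-13, and adjusted p = 0.232 with an estimated correlation). On the hard gel they fell in 15 and rose in 7 cases, or 18 and 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0147, and adjusted p = 0.54 with an estimated correlation). Immediate early genes fell in 10 and rose in 1 of 16 cases on soft and fell in 16 of 16 on hard gels (camera, Benjamini-Hochberg adjusted p = 0.000131 and 5.5e-15, and adjusted p = 0.367 and 0.179 with an estimated correlation). Actin genes fell in 16 of 20 cases on soft and 18 on hard gels (camera, Benjamini-Hochberg adjusted p = 2.68e-09 and 3.14e-13, and adjusted p = 0.235 and 0.179 with an estimated correlation). Hypoxia genes fell in 10 of 11 cases on each gel, with a median log2 of -0.62 on both (camera, Benjamini-Hochberg adjusted p = 7.18e-08 and 6.81e-09, and adjusted p = 0.22 and 0.179 with an estimated correlation). Interferon genes fell in 11 of 18 cases on soft and 10 on hard gels, where 1 rose (camera, Benjamini-Hochberg adjusted p = 0.000121 and 5.65e-05, and adjusted p = 0.336 and 0.287 with an estimated correlation). Glycolysis genes fell in 14 of 22 cases on soft and 10 on hard gels (camera, Benjamini-Hochberg adjusted p = 1.64e-06 and 5.98e-07, and adjusted p = 0.266 and 0.227 with an estimated correlation). Mitochondrially encoded genes fell in 13 of 13 cases on soft and 5 on hard gels (camera, Benjamini-Hochberg adjusted p = 1.14e-05 and 0.00598, and adjusted p = 0.266 and 0.42 with an estimated correlation). CALCRL rose on the soft gel from 14.5 ± 1.45 to 60.9 ± 1.18 CPM (SD, n = 3), while PDE3A changed by log2 -2.32 on soft and -2.13 on hard gels. On soft gels MMP10 rose by 1.89 and the carboxypeptidase CPA4 changed by -1.98. On hard gels FOSB changed by -2.08. In all, edgeR called 5705 genes on soft gels, 2795 up and 2910 down, and 4379 on hard gels, 2050 up and 2329 down. Time and culture batch cannot be separated by the labels.

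In mouse cells on the hard gel, the monocyte-attracting chemokines Ccl7 and Ccl2, the leukocyte receptors Vcam1 and Selp and the YAP target Ctgf rose. Basement membrane collagens (Col4a1, Col4a2), the integrin Itgb3 and the proton-sensing receptor Gpr4 also rose. The chaperones Hspa1a and Hspa1b, the stress factor Atf3 and the growth factor Bmp2 fell.

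Leukocyte adhesion genes rose in 5 of 10 cases, also when adjusted over the list alone, with 0 falls (camera, Benjamini-Hochberg adjusted p = 0.0011, and adjusted p = 0.27 with an estimated correlation). Selp rose by log2 0.61 and Vcam1 from 98.7 ± 2.68 to 144 ± 11.6 CPM (SD, n = 3). Chemokines rose in 3 of 12 cases and in 4 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0041, and adjusted p = 0.596 with an estimated correlation). Ccl7 (mm10 chromosome 11, 82045712 to 82047523) rose 1.97-fold, from 96.6 ± 11 to 189.9 ± 26.9 CPM (SD, n = 3), and Ccl2 from 1385 ± 117 to 2181 ± 132 CPM. Cxcl1 was not called at log2 0.25 (edgeR, Benjamini-Hochberg adjusted p = 0.0562), but was with the replicate block (adjusted p = 0.0037), and Cxcl2 was not called at -0.02. NF-kB targets rose in 4 of 21 cases and integrin genes in 3 of 19, or 7 and 7 when adjusted over the list alone, with 0 falls in both. Each list had a camera Benjamini-Hochberg adjusted p = 0.000182, and adjusted p = 0.449 and 0.179 with an estimated correlation. Itgb3 rose from 968.6 ± 43.6 to 1254 ± 42.8 CPM (SD, n = 3), Tnfaip3 by log2 0.27 and Tns3 by 0.29.

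Capillarization and basement membrane genes rose in 3 of 11 mouse cases and in 6 when adjusted over the list alone, with Col4a1 and Col4a2 at log2 0.42 and 0.44 (camera, Benjamini-Hochberg adjusted p = 0.00638, and adjusted p = 0.429 with an estimated correlation). Interferon genes rose in 2 of 16 cases and in 10 when adjusted over the list alone, with Usp18 at log2 0.80 and Ddx58 at 0.50 (camera, Benjamini-Hochberg adjusted p = 2.34e-05, and adjusted p = 0.596 with an estimated correlation). Genes of the unfolded protein and integrated stress response fell in 3 of 14 cases and in 6 when adjusted over the list alone, with Atf3 at log2 -0.39 and Dnajb9 at -0.29 (camera, Benjamini-Hochberg adjusted p = 1.93e-05, and adjusted p = 0.179 with an estimated correlation). Heat shock genes fell in 3 of 10 cases and in 7 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000182, and adjusted p = 0.429 with an estimated correlation). Hspa1a and Hspa1b changed by log2 -0.77 and -0.81, but near-identical copies make both uncertain. Hepatocyte markers had a median log2 of -0.31 over 17 genes, with 0 of them called by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 4 lower with the replicate block (camera, Benjamini-Hochberg adjusted p = 0.0329, and adjusted p = 0.786 with an estimated correlation). Hypoxia genes fell in 1 of 10 cases, Ndrg1 at log2 -0.28 (camera, Benjamini-Hochberg adjusted p = 0.0329, 0.107 with the replicate block, and adjusted p = 0.541 with an estimated correlation). With the block, sterol synthesis and tip cell genes were called as lists (camera, Benjamini-Hochberg adjusted p = 0.0405 and 0.0145 against 0.0561 and 0.112 without it). Without the block, both had no call with an estimated correlation (adjusted p = 0.596 and 0.667; camera, Benjamini-Hochberg).

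Of 21 mouse YAP and TEAD targets 1 rose and 1 fell, and 4 and 1 when adjusted over the list alone, without a call for the list (camera, Benjamini-Hochberg adjusted p = 0.138). Ctgf (chromosome 10, 24595442 to 24598682) rose from 41.9 ± 4.98 to 80.7 ± 9.26 CPM (SD, n = 3), and Gadd45a changed by log2 -0.30. Cyr61 was not called at log2 0.39 (edgeR, Benjamini-Hochberg adjusted p = 0.163), but was with the replicate block (adjusted p = 0.0011), and Ankrd1 was not called at 0.30. Gpr4 (chromosome 7, 19212538 to 19224176) had a log2 fold change of 0.90 (SE 0.0602; edgeR, Benjamini-Hochberg adjusted p = 7.84e-05). Sinusoidal markers rose in 1 of 12 cases, Lyve1 from 3117 ± 69 to 3553 ± 80.2 CPM (SD, n = 3), while Stab1 and Stab2 were not called at log2 0.01 and 0.04. Of 19 glycolysis genes 0 rose and 1 fell, Pfkfb4 at log2 -0.39, and Hk2, Pfkfb3 and Ldha were not called at 0.09, 0.13 and 0.13 (camera for the list, Benjamini-Hochberg adjusted p = 0.766). Actin genes rose in 1 of 20 cases, Actn1 at log2 0.30, and nuclear pore genes in 0 of 28 by edgeR (1 up and 1 down at an unadjusted p under 0.05, 0 by DESeq2; camera, Benjamini-Hochberg adjusted p = 0.112 and 0.83). Matrix genes were called by edgeR in 0 of 19 cases (4 up and 2 down at an unadjusted p under 0.05, 1 up by DESeq2; camera, Benjamini-Hochberg adjusted p = 0.25).

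In all, edgeR called 304 mouse genes, 141 up and 163 down, of which 4 and 1 changed at least by log2 1, and 894 with the replicate block (432 up and 462 down). Psg22, Cdc42ep2 and Bcl6b were further rises at log2 0.79, 0.78 and 0.68. Gla, Sstr5, Myo18b, Star and Atad2 were among the further falls, between log2 -0.66 and -0.63. The groups did not overlap in 2749 genes, 19.5% of those tested, where chance gives 10%. The count was 101 without soft replicate 1, 202 without soft replicate 2, 149 without hard replicate 2 and 54 without hard replicate 3. Without soft replicate 1 or hard replicate 3 the calls of Usp18, Pfkfb4, Tnfaip3, Gadd45a, Actn1, Tns3, Lyve1, Ndrg1, Dnajb9 and Ddx58 ended, and without hard replicate 3 also those of Col4a2, Atf3 and Cd68. Calls also ended without soft replicate 2 (Lyve1, Gadd45a, Pfkfb4, Tns3, Dnajb9), soft replicate 3 (Lyve1, Gadd45a, Usp18, Ddx58), hard replicate 1 (Dnajb9) and hard replicate 2 (Lyve1, Gadd45a, Usp18, Tnfaip3, Ndrg1, Dnajb9, Ddx58), so the rise of Lyve1 was kept in 1 of these 6 fits. Leaving out both libraries numbered 3, chosen after the result was seen, ended 14 of 25 calls, those of Vcam1, Itgb3, Hspa1a and Hspa1b among them. The fewest called list members were 2 leukocyte adhesion, 1 NF-kB and 1 integrin genes without soft replicate 1, and 1 capillarization and 0 stress response genes without hard replicate 3. Interferon genes numbered 0 without soft replicate 1 or 3 or hard replicate 2 or 3, 4 without soft replicate 2 and 9 without hard replicate 1.

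**Figure D4:**
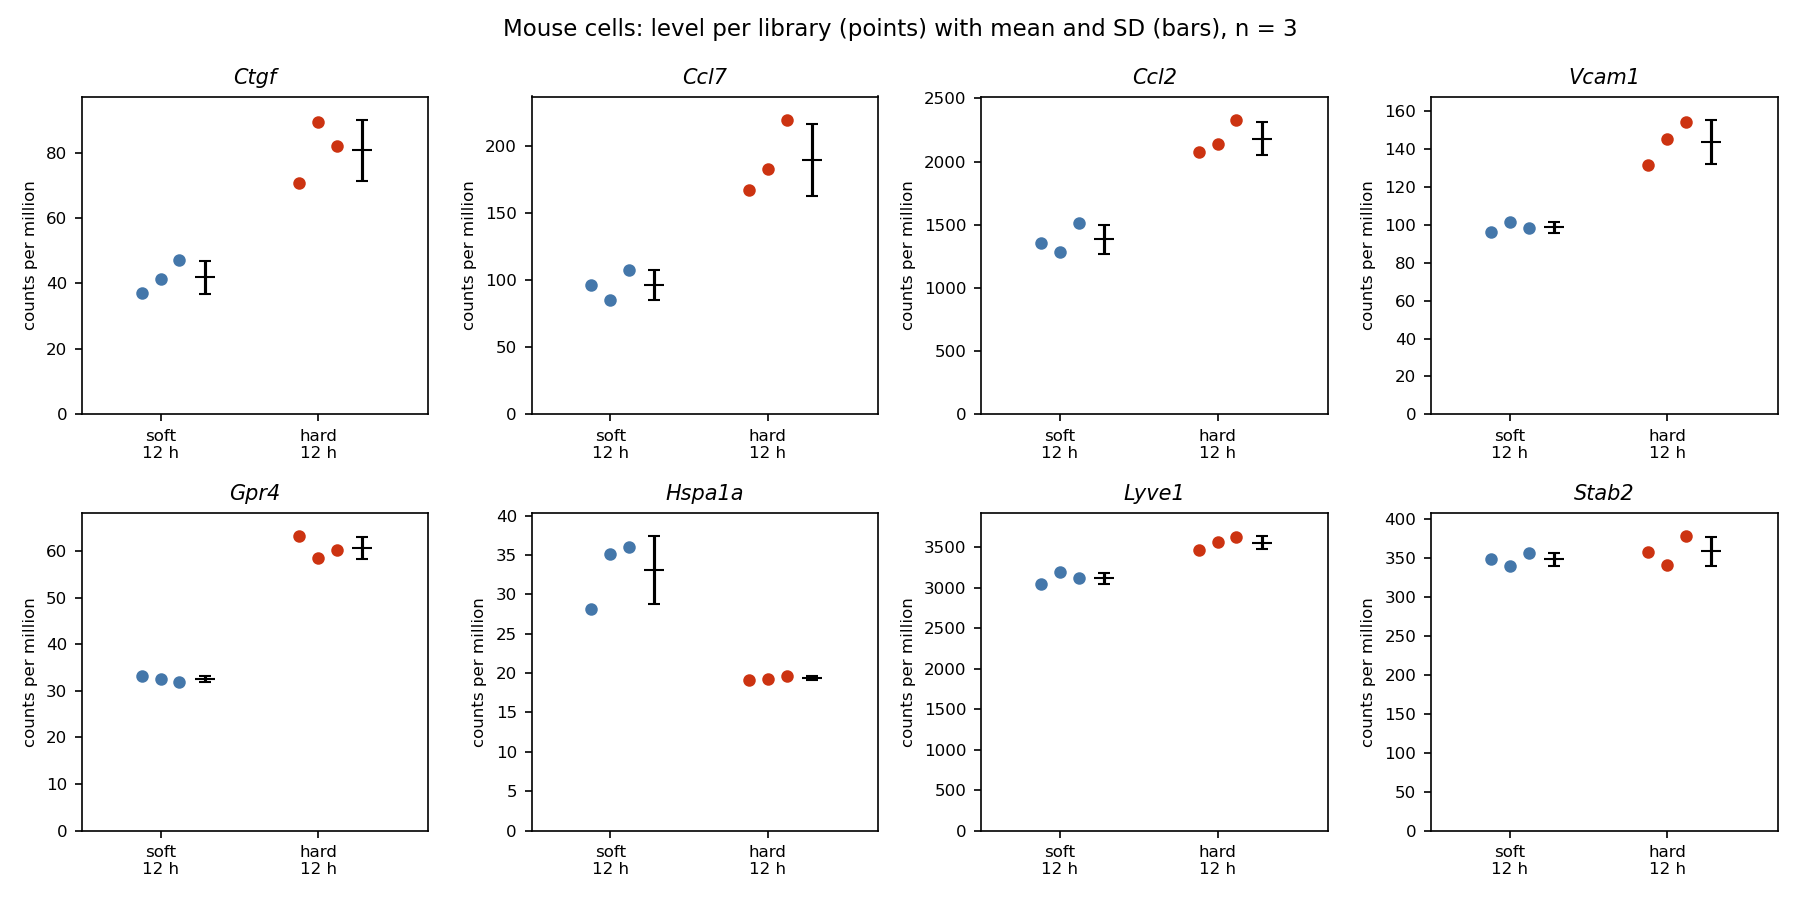
CPM per mouse library of 8 genes on soft (blue) and hard (red) gels at 12 h, with bars for the mean ± SD of 3 libraries. Ctgf averaged 80.7 CPM on hard against 41.9 CPM on soft gels and Hspa1a 19.3 CPM against 33.1 CPM.

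Between the species, CTGF (log2 1.66 in human and 0.95 in mouse) led the shared rises, ranked by the smaller of both effects. GPRC5B, the ephrin receptor EPHA2, the smooth muscle protein SMTN and the activin antagonist FST also rose in both, FST by 1.07 and 0.41. The cholesterol exporter ABCA1 (-0.54 and -0.51), the transferase GSTA4 (-0.54 and -0.48), TCP11L2, PTGR1 and FLCN fell in both. Across 10136 genes paired by symbol, the gel effects at 12 h correlated with Pearson r = 0.0687 and Spearman rho = 0.0976. In the exact count over 100 splits, on differences of mean log2 CPM, 17 reached the r = 0.0695 of the real one (highest other 0.191, exact p = 0.17). Over the 40 splits that part all mouse pairs of equal number, a count chosen after the result was seen, 8 reached it (highest other 0.140, exact p = 0.2). Genes called in both species numbered 110, with 41 higher, 34 lower and 35 opposite, where independence gives 19.4, 16.9 and 36.6. Of all 253 paired genes called in mouse, only 139 (54.9%) changed the same way in human, called there or not.

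The authors' deposited tables gave close fold changes. Across 20137 human genes at each time and 14019 mouse genes, Pearson correlations with the log2 fold changes in the authors' deposited tables were 0.999925, 0.999947 and 0.999974. The authors' deposited tables call 2243, 3132 and 543 genes at an adjusted p under 0.05. Among the matched genes they call 2116, 2969 and 508, of which 1999, 2938 and 301 were also called here, all with the same sign.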

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

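Of the tests in this part, those on the number of mouse libraries, on their spread, on the replicate block and on other splits were chosen only after the result was seen. The gel effect differed between 6 h and 12 h, by the edgeR interaction test with Benjamini-Hochberg adjustment, for the genes that follow. It was larger at 12 h for SLC8A1 (difference of log2 1.24), MCM10 (1.18), AOX1 (1.16), HELLS (1.11) and CLSPN (1.07). It was lower at 12 h for EDN1 (-1.34), IL11 (-1.07), EGR1 (-0.99), EGR3 (-0.96), NR4A1 (-0.86) and EGR2 (-0.81). The YAP and TEAD targets CTGF (-0.70) and CYR61 (-0.67) kept a rise at both times that was smaller at 12 h. NFKBIZ (-0.35) and NFKB1 (-0.42) had lower gel effects at 12 h, and MGP (-0.96) and PDGFRB (-0.59) larger falls. Further called differences were those of RRM2 (0.96), MCM4 (0.72), ATAD2 (0.56), NEDD9 (-0.77), FOS (-0.72), SPP1 (-0.70) and KRT18 (-0.37).

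For the interaction, 100 splits of the human libraries were used, the real one and others drawn at random from all possible ones. Of these, 7 called at least as many interaction genes as the real 177, with 1479 as the highest other. The splits therefore do not exclude chance for this count. All 6 others kept the 12 h libraries in their gel groups and mixed the 6 h libraries. Their contrast therefore carries the gel effect at 12 h itself, a structure of the samples. For the other counts 1 of 10 splits, the real one, reached the count, and 10 splits are too few for a share under 0.05. The real counts were 2500 and 4263 for the gel at 6 h and 12 h, 5705 and 4379 for time on soft and hard gels, and 304 in mouse, with 0 as the highest other each time. Of the mouse splits, 4 part all 3 pairs of equal number, and the 3 of these other than the real one called 0 genes by edgeR with and without the block.

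The gel effect went opposite ways in human and mouse cells at 12 h for the genes that follow, each with every hard library on one side of the soft ones, but the difference between the species was not tested. RNF144A rose by log2 0.56 in mouse and changed by -1.18 in human. TNS3 rose by 0.29 in mouse and changed by -0.46 in human. ATAD2 (-0.63 and 0.91) and GADD45A (-0.30 and 0.32) fell in mouse and rose in human.

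The mouse cells had 304 genes called at 12 h against 4263 in the human cells, with a median absolute log2 fold change of 0.0783 against 0.133 among genes with a mean log2 CPM of at least 3. Fewer libraries in the fit are argued against by 3855 human genes called with the 6 human 12 h libraries alone, and lower depth by 3650 called with these thinned to the smallest mouse total. A wider spread is argued against by the median SE, which in mouse was 0.949 times that in the 6 human 12 h libraries. The biological coefficient of variation was nevertheless higher in mouse, 8.46% against 7.06% over the 12 human libraries. With the replicate block, 894 mouse genes were called instead of 304, and 2862 human genes instead of 3855 in the fit of the 6 libraries. Variation shared by libraries of equal number may thus account for a part of the gap. A gap remained with the block, near the limit of that test. A smaller response of the mouse cells may remain as a hypothesis, found and tested on the same data. Species differ here together with marker levels that put the identity of the human cells in doubt. Cell source and culture may differ too, but the culture of the mouse cells is not given. All of these stay open, as untested.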

How the results depend on the processing

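Leaving out both mouse libraries of a number was chosen only after the result was seen, and all other alternatives were planned. Size factors by the median of ratios and a strict filter (1 CPM in 3 libraries) left all 6 counts of called genes within 1.5 times their value. Of 118 calls of named genes, those taken only from lists outside the study's question aside, 105 were kept in all planned settings other than the fold limit, under which single genes were not counted, with 43 of 1441 values losing the call and 0 reversed.

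With a fold limit of log2 1, the counts became 150 and 272 for the gel at 6 h and 12 h, 658 and 526 for time on soft and hard gels, 21 for the interaction and 5 in mouse, as the limit's construction requires. With DESeq2, the interaction called 417 genes and mouse 621, and without a filter 479 and 460; the cause was not tested. With the replicate block, the interaction called 89 genes and mouse 894. The human libraries of equal number showed no positive correlation, so the block spends degrees of freedom there. In mouse these correlations were positive, although the check does not establish pairing.

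Camera with an estimated correlation called 0 lists in human at 6 h, 0 at 12 h and 0 in mouse, against 12, 13 and 10 with the preset one. At an unadjusted p under 0.05 the estimated correlation gave 7, 6 and 4 lists, while fry called 15, 14 and 5. In called lists the estimate ran from -0.0180 to 0.908; the cause was not tested.

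The correlation of gel effects between 6 h and 12 h was 0.731 over genes with a mean log2 CPM of at least 3, 0.926 over genes called in both, 0.647 over genes called in either and 0.440 by Spearman. Between human and mouse these were 0.151, 0.378, 0.105 and 0.0976. Called genes are chosen for their size by construction, and for the floor the cause was not tested.

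Leaving out each library in turn gave 1450 to 2382 genes at 6 h, 2894 to 4695 at 12 h, 4397 to 6190 and 3339 to 3688 for time on soft and hard gels, 72 to 603 for the interaction and 54 to 374 in mouse. A pair of libraries was left in an arm and the spread was pooled. The lists called ranged from 11 to 14, 13 to 14 and 9 to 12, and the correlations from 0.337 to 0.382 and from 0.0433 to 0.0760. The interaction rose to 603 without soft 12 h replicate 3, and the cause was not tested. Leaving out both mouse libraries numbered 1, 2 or 3 gave 90, 127 and 27 genes, with fewer samples.

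Depth limits genes near the filter, such as STAB2 in human cells, more than the abundant genes named here. Simulated changes of log2 0.5 were called in 97%, 96% and 93% of cases, but only among genes with a mean log2 CPM of at least 3. Genes near the filter were not covered.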

Other observations

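Of the tests in this part, that on the share of fibroblast-like cells was chosen only after the result was seen. Several endothelial programmes outside the main pattern held single genes that changed in human cells, although camera called none of the 4 lists that follow. Notch pathway genes rose in 2 and fell in 1 of 11 cases at 6 h, and rose in 1 and fell in 3 at 12 h, with the arterial ligand EFNB2 at log2 0.33 and 0.48 and HEY1 at -0.79 and -0.63. The KLF2 list had 1 rise of 6 at each time, KLF2 itself at 0.71 and 0.52. Genes of the endothelial to mesenchymal transition rose in 1 and fell in 2 of 11 cases at 6 h, and rose in 2 and fell in 4 at 12 h. In this list the cadherin CDH2 stood at 0.33 and 0.50 and SNAI1 at -0.41 and -0.52. Hypoxia genes rose in 2 and fell in 3 of 11 cases at 6 h, and rose in 3 and fell in 5 at 12 h, with the mTOR inhibitor DDIT4 at -0.48 and -0.40.

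These counts moved when a library was left out. Rising hypoxia genes numbered 1 without any library of 6 h, and at 12 h 0 without hard replicate 1 and 1 without soft replicate 1 or 2 or hard replicate 3. Falling ones at 12 h numbered 2 without hard replicate 2 and 3 without soft replicate 1 or 2. Falling genes of the endothelial to mesenchymal transition numbered 2 at 12 h without soft replicate 2 or hard replicate 1 or 2, and 1 at 6 h without soft replicate 1 or hard replicate 1 or 2. Rising Notch genes at 6 h numbered 1 without replicate 1 or 2 of either gel, and falling ones 2 without soft replicate 2 or hard replicate 1. At 12 h, rising Notch genes numbered 2 without hard replicate 1 and falling ones 5 without hard replicate 3.

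Markers of other liver cells were measured beside these. In human cells, cholangiocyte and epithelial markers rose in 2 of 8 cases at 6 h, the keratins KRT18 and KRT8 at log2 0.42 and 0.26, and fell in 2 at 12 h, SPP1 and SOX9, SOX9 at -0.30. The 12 h count was 1 without soft replicate 1 or 2 or hard replicate 2. The macrophage receptor CSF1R was lower at 6 h, at -0.59. The call of SOX9 ended in 5 alternative settings and that of CSF1R in 7, the fit of the 6 libraries compared alone among them. In mouse cells, edgeR called 1 of 15 macrophage markers, Cd68 at -0.52, and 0 of 10 cholangiocyte markers, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Mouse albumin (Alb) ranged from 159 to 433 CPM between libraries.

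Stellate cell and fibroblast markers fell on the hard gel in human cells at 12 h, in 6 of 12 cases (3 without soft replicate 2), with a median log2 of -0.25 and PDGFRB (-0.94) and DCN (-0.50) in front (camera, Benjamini-Hochberg adjusted p = 0.00277, and adjusted p = 0.402 with an estimated correlation). The fall was not limited to 12 h. At 6 h DESeq2 called 4 of the 12 lower and 0 higher, and each fit without 1 library kept 4 lower. A smaller share of fibroblast-like cells would lower their markers alike only if other cells lacked them and no marker itself responded to the gel. At 12 h, effects ran from -0.94 to -0.07 over 8 abundant markers, with a Cochran Q of 12.7 times its degrees of freedom. Whether other cells here lacked these markers was not tested, so the unequal falls cannot decide on a change of share. All 8 markers fell, so a smaller share, alone or together with other changes, stays open. With size factors by the median of ratios the list had a median of -0.24. That scaling shifted the fold changes of all genes by a median of only 0.00425, so it could not test the size factors. The human libraries held 12 of the 14 markers above the filter, with COL1A1 at 14203 CPM and COL1A2 at 10640.3 CPM. A change of these genes within the cultured cells may remain as a hypothesis, and which cells carried them stays open.

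Cytosolic ribosomal protein genes fell while nuclear pore genes rose on the hard gel in human cells at 12 h, in 11 of 22 and 15 of 27 cases, with medians of -0.15 and 0.18 (camera, Benjamini-Hochberg adjusted p = 1.89e-06 and 1.89e-08, and adjusted p = 0.387 and 0.0613 with an estimated correlation). Gene length bias is argued against by medians of -0.17 and 0.17 after each library's trend with length was removed, although the Spearman correlation of all fold changes with length was only -0.0215, so there was little trend to remove. GC content bias is argued against by medians of -0.16 and 0.16 after the same correction for GC, although the fold changes of all genes had a Spearman correlation of -0.209 with GC. A shift in these classes with the gel may be a candidate explanation, and RNA quality and culture density stay open, as untested.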
